A study of Homo sapiens with 6 samples.

How the data were processed

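RNA was measured on 6 one-colour Affymetrix GeneChip arrays, 1 for each of 3 conditions in each of 2 human gastric cancer cell lines, AGS and HGC-27. Per the labels' protocols, cells were nucleofected with 3 µg of MIST1 plasmid or empty vector together with 1.5 µg of a GFP plasmid. They were sorted 24 h later, grown for another 24 h and then harvested, and 5 µg of total RNA per array was labelled with a one-cycle kit. The series design text gives the sorting criterion as GFP fluorescence, applied to both transfected populations. Parental cells were not transfected, and no label says that they were sorted. The authors deposited 1 value per probe set and array, and these values were read as linear-scale intensity because they ran from 0.48 to 19070.5. The series design text names dChip as the analysis program. Whether the deposited intensity values are dChip model values, and which background correction and between-array scaling they carry, is not given in the sources used here.

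The array holds 54675 probe sets. In the platform annotation 41097 of them have 1 gene, 1801 have several and 11777 have none listed. For 41043 single-gene probe sets the symbol was updated through the gene ID, and no gene was named from a probe set with several genes. The 62 control probe sets, XIST and Y-linked genes were left out of the tests. Array medians of the deposited intensity lay between 49.12 and 51.96, and the largest difference of their log2 values was 0.08. Since that was within the limit of 0.1 set before the data were examined, the deposited values were used without further scaling. They were set to a floor at the 25th percentile of all values, 17.6, and then taken to log2. Probe sets were kept where at least 2 of the 6 arrays lay above the median of all values, 50.53, which left 25933 single-gene probe sets. A gene was represented by its probe set with the highest mean over the 6 arrays, giving 13730 genes. Over these genes the arrays were less alike, with log2 medians from 8.22 (HGC-27 parental) to 8.50 (AGS parental). The HGC-27 GFP control was at 8.40 and the HGC-27 MIST1 array at 8.34. A change measured against a value at the floor is understated. Probe sets whose names end in _x_at can cross-hybridize with other transcripts, which among the named genes applies to CCPG1, COX3, ATP8B1, ALMS1, CENPA, CELA3A, HSP90B1, KRT18, COL3A1 and MAGEA6. The number of arrays, not a read depth, limits the precision of these values.

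Each condition has 1 array per line, so the 2 cell lines are the replicates. The labels tie the 3 arrays of a line together, and cell line was a block in every comparison of conditions. Over the genes tested, arrays of the same line correlated at 0.97 or higher (Pearson r from 0.971 to 0.996), and arrays of different lines at 0.70 to 0.73. Comparisons used limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on all 6 arrays, which left 2 residual degrees of freedom and 4.47 prior degrees of freedom. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. P-values of the comparisons of conditions therefore measure the spread between single arrays of 2 cell lines, which mixes technical variation with differences between the lines. For AGS against HGC-27 the 3 conditions of a line stand in for replicates. Those p-values do not measure variation between cultures of a line under 1 condition. A fit of only the 4 arrays of the 2 conditions compared was an alternative chosen in advance, with 1 residual degree of freedom and, for MIST1 against the GFP control, 9.01 prior degrees of freedom.

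The study's Boolean comparisons were followed with a count. A gene passed upward when its MIST1 value was at least 1.5-fold the GFP control and at least 1.5-fold the parental value in both lines, with both MIST1 values above the median. The downward rule was its mirror, with all 4 control values above the median. The fold limit is not in the labels and was set here. The same count was made for each of the 9 ways of taking 1 array per line as the odd one.

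There were 19 gene lists, fixed before the data were examined: MIST1-linked genes, zymogenic and exocrine products, Rab GTPases and exocytosis machinery, unfolded protein response, ATF4 and amino acid stress, interferon response, inflammatory NF-kB targets, heat shock and immediate early genes, p53 targets, mitotic genes, DNA replication genes, histone genes, cholesterol synthesis, hypoxia and glycolysis, bHLH and ID factors, epithelial genes, mesenchymal genes, gastric and intestinal lineage genes, and leukocyte and endothelial genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation, camera tests on the 2 residual degrees of freedom, so few lists can pass. A high adjusted p there does not show that correlation explains a result. For the MIST1-linked genes the estimated correlation was -0.12, below the preset. It was also below it for cholesterol synthesis, at -0.02, and for the Rab and exocytosis list, at -0.005. For mitotic genes it was 0.36, and for the unfolded protein response and the ATF4 list 0.43 each. Those estimates lie far above the preset, so the camera p-values of these lists at the preset are likely too small. Some fixed symbols have no single-gene probe set under that symbol in the annotation and were not analysed here.

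The genes named were set by a rule written before the data were examined. It takes BHLHA15, RAB26 and RAB3D first. For MIST1 against the GFP control it takes the 12 rising and 12 falling genes with the largest change among those past the threshold with the same direction in both lines, with empty places filled from the Boolean list in order of the smallest of its 4 changes. For the other comparisons it takes the 8 genes with the largest rise and the 8 with the largest fall past the threshold that keep their direction in both lines, or in all 3 conditions for the comparison of lines. From a fixed list it takes up to 4 members with the largest change in MIST1 against the GFP control, or between the lines for the 3 lineage lists. Members were named for the lists past the threshold in that comparison and for the lists of secretory genes. Any gene named outside this rule is said to be so.

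The code was tested on 20 simulated sets of arrays for MIST1 against the GFP control, with 13730 genes, the gene means of the real arrays, spreads drawn from the variance prior fitted to them, and 200 changed genes. The limma test called 55.4% of the genes changed 2-fold and 94.3% of those changed 4-fold, with a mean of 7.7 false calls per set. The Boolean rule returned 80.4% of the genes raised 2-fold and 99.6% of those raised 4-fold. In sets with no changed gene the rule returned a mean of 7.95 genes upward, 13 at most, and a mean of 5.85 downward. The simulated sets had the same spread in every condition and no difference between parental and transfected arrays. These rates and counts therefore do not carry over directly to the real arrays. Alternatives covered quantile normalization, the floor, the filter, the probe set of a gene, the variance trend, the block, the arrays in the fit and each array left out in turn, where the lone array of a condition is assumed to vary like the other conditions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.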

Results

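The series asked which genes are raised by transient expression of MIST1, the basic helix-loop-helix transcription factor encoded by BHLHA15 that marks mature zymogenic and acinar secretory cells. Expression was measured in AGS, a gastric adenocarcinoma line, and HGC-27, an undifferentiated gastric carcinoma line. Each line gave 1 array of untransfected parental cells, 1 of cells sorted after transfection with GFP and empty vector, and 1 of cells sorted after transfection with GFP and MIST1. Values are deposited probe set intensities, and each gene has 2 measurements of a change, 1 per line. There were no replicates within a line.

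The probe set for BHLHA15 itself did not separate the arrays labelled MIST1 from the controls. In AGS it read 66.3 in parental cells, 75.9 in the GFP control and 72.5 in the array labelled MIST1. In HGC-27 it read 41.1, 61.9 and 58.7. The change over the GFP control was -0.07 on the log2 scale in AGS and -0.08 in HGC-27. The labels do not say which species or which untranslated regions the construct carries, so this probe set may not read it, and it checks neither the labels nor the level of MIST1. RAB3D and RAB26, small GTPases of secretory vesicles, were both higher in the arrays labelled MIST1. RAB3D read 540 in the GFP control and 1308 with MIST1 in AGS, and 504 and 1783 in HGC-27. RAB26 read 70.9 and 149 in AGS, and 122 and 227 in HGC-27.

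With MIST1 against both controls in both lines, 17 genes were at least 1.5-fold higher and 0 genes were at least 1.5-fold lower. RAB3D was 2.42-fold above the GFP control in AGS and 3.53-fold in HGC-27. SERPINI1, which encodes the secreted protease inhibitor neuroserpin, was 4.11-fold and 2.16-fold above it, and RAB26 2.11-fold and 1.86-fold. TIFA, an adaptor of NF-kB signalling, was 2.13-fold and 1.83-fold higher. ARRDC3, an arrestin-domain protein, was 2.36-fold and 1.87-fold higher. CCPG1, a receptor for autophagy of the endoplasmic reticulum, was 1.65-fold and 2.21-fold higher, by a probe set whose name marks possible cross-hybridization. AKAP19 was 1.75-fold and 2.77-fold higher, and FIGN, which encodes the microtubule-severing protein fidgetin, 1.75-fold and 1.63-fold. KIAA0513 was 2.03-fold and 1.85-fold higher. Of the 17 genes, 11 in AGS and 16 in HGC-27 were already higher in the GFP control than in parental cells. The median of this log2 change was 0.20 in AGS and 0.34 in HGC-27, against 0 and 0.13 over all genes tested. This change without MIST1 was 0.68 and 1.78 on the log2 scale for KIAA0513. For SERPINI1 it was -0.47 in AGS and 1.66 in HGC-27.

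Of the other genes passing this rule, IQCN, PRODHLP, ARHGAP30 and TMEM132D were dim, at most 77.7 in any array, and did not pass with the floor at the median. IQCN was 1.87-fold and 2.13-fold above the GFP control in AGS and HGC-27, the pseudogene PRODHLP 1.85-fold and 1.84-fold, and ARHGAP30 1.77-fold and 2.05-fold. The parental value lay under the floor for PRODHLP in AGS and for ARHGAP30 in HGC-27, so their folds over parental cells are lower bounds. The other 5 genes lie outside the naming rule and were chosen after their values were seen. These were ACP2, a lysosomal acid phosphatase, at 1.79-fold and 2.27-fold, SLC31A2, a copper transporter, at 1.54-fold and 2.94-fold, and MPC1, a subunit of the mitochondrial pyruvate carrier, at 1.57-fold and 1.53-fold. DISP2 was 1.51-fold and 2.86-fold higher, and TMEM132D, which did not pass after quantile normalization, 1.58-fold and 1.54-fold. Of the 17 genes, RAB3D, KIAA0513, RAB26, TIFA, AKAP19 and FIGN had 8 other probe sets in all that passed the filter. All 8 were higher with MIST1 in both lines, 6 of them by at least 1.5-fold, though the 2 MIST1 arrays alone can meet the filter. Of 6 dim probe sets of the 17 genes that the filter left out, 2 were higher in both lines.

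The count of 17 genes is for a rule without a test. Taking both parental arrays as the odd ones gave 140 genes higher and 240 lower than the transfected arrays, and the 7 choices that mixed conditions or took both GFP arrays gave at most 4 genes. The limit decided much of the count, since 102 genes passed upward and 41 downward at 1.2-fold, where the highest mixed choice of arrays gave 56 and the GFP arrays gave 31, and 2 genes, RAB3D and SERPINI1, passed upward at 2-fold. Leaving out an array drops its comparisons, so the upward count became 30 without the AGS GFP control, 29 without the HGC-27 GFP control, 76 without the AGS MIST1 array and 69 without the HGC-27 MIST1 array. The downward count became 8, 3, 35 and 18 in the same order, and 1 without the HGC-27 parental array.

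**Figure D1:**
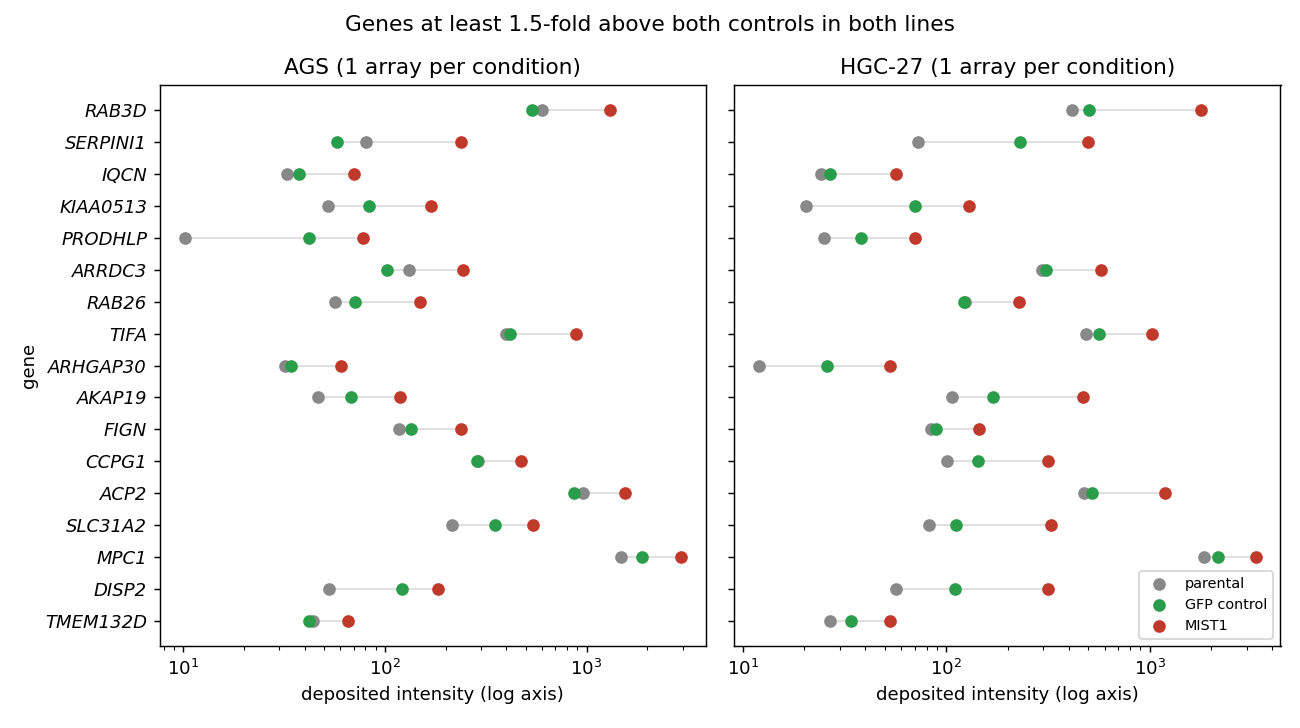
Deposited intensity (log axis) of the 17 genes that were at least 1.5-fold above both controls in both lines, in AGS (left) and HGC-27 (right). Each point is 1 array, grey for parental, green for the GFP control and red for MIST1, and the red point is the highest in each row, as for RAB3D at 1308 in AGS and 1783 in HGC-27.

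In the limma comparison of MIST1 with the GFP control over all 6 arrays, no single gene passed. The count was 0 of 13730 genes after Benjamini-Hochberg adjustment, with 184 genes at an unadjusted p under 0.05 where chance gives 686. This fit shares 1 spread with the parental arrays. The SD over genes was 0.43 (AGS) and 0.49 (HGC-27) for GFP control over parental, and 0.20 and 0.22 for MIST1 over GFP control. The shared spread is likely too wide here and the p-values too large, so the count of 0 is not evidence of no change. The SE of RAB3D was 0.11 with only the 4 arrays compared. RAB3D was higher by 1.55 on the log2 scale (SE 0.23, n = 2 lines, limma adjusted p = 1), SERPINI1 by 1.58 (SE 0.45) and RAB26 by 0.99 (SE 0.19). The count rose to 55 genes, 51 higher and 4 lower, in the planned fit of the 4 arrays compared, where 1730 genes had an unadjusted p under 0.05. The 17 genes above were picked partly on the same 4 arrays, so their overlap with these calls is not independent evidence. The 4-array fit included 13 of the 17. It gave a limma adjusted p of 0.000479 for RAB3D and MPC1, 0.000609 for TIFA, 0.000618 for ACP2, 0.0031 for ARRDC3 and 0.00793 for RAB26. Outside the naming rule, it also called UAP1, an enzyme of UDP-N-acetylglucosamine synthesis, which was higher by 0.78 (adjusted p = 0.000609). The 4 lower genes, also outside the rule, were TNNC1 at -0.58, PLGRKT at -0.50, MDK at -0.37 and TMEM205 at -0.34. In the fit of all conditions TNNC1 was at 0.0023 without the HGC-27 GFP control. The 6-array count was 57 without the AGS parental array and 51 without the HGC-27 parental array. It was 1 without the AGS GFP control, 3 without the HGC-27 GFP control, 13 without the AGS MIST1 array and 5 without the HGC-27 MIST1 array.

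The 2 lines shared part of the change with MIST1. Across the 13730 genes, which are not independent replicates, the change over the GFP control in AGS and in HGC-27 correlated at Pearson r = 0.21 and Spearman rho = 0.23, and 57.2% of genes had the same sign. No array enters both changes. At 1.5-fold or more, 29 genes were higher in both lines where independent lists would share 1.95. By the same count 3 genes were lower in both lines where 1.12 would be shared, and 8 went opposite ways where 3 would. The correlation was 0.13 with no filter on dim probe sets.

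**Figure D2:**
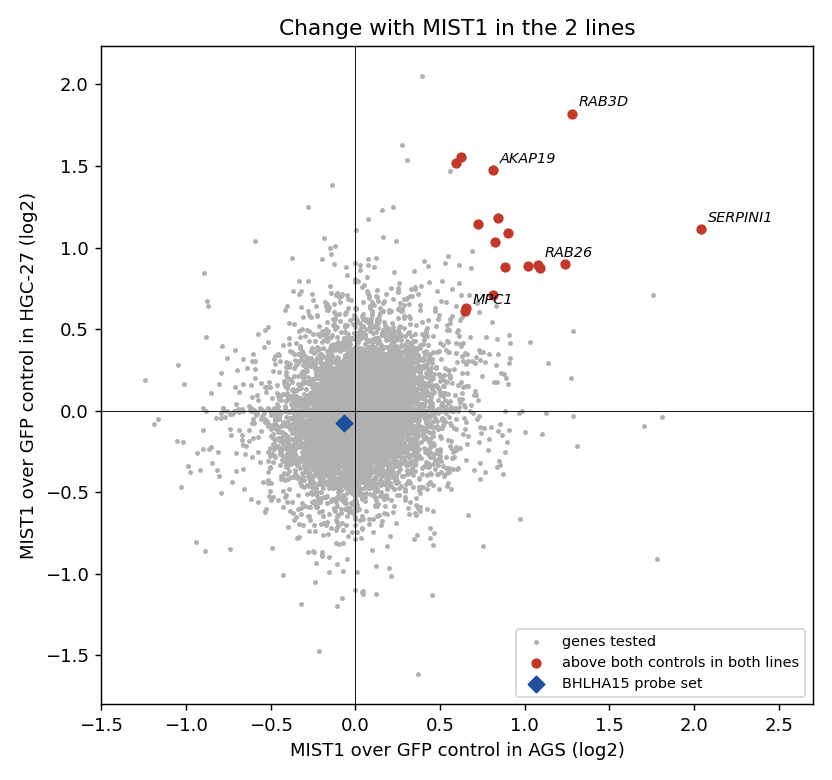
Change of MIST1 over the GFP control on the log2 scale in AGS (horizontal axis) and HGC-27 (vertical axis), 1 grey point per gene tested. The 17 genes above both controls in both lines are red, with RAB3D and SERPINI1 farthest out, and the BHLHA15 probe set (blue diamond) lies at -0.07 and -0.08.

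Among the 19 fixed lists, the MIST1-linked genes and the mitotic genes were higher with MIST1 than in the GFP control. Of 7 measured MIST1-linked genes, 0 passed over all genes and 3 rose when adjusted over the list alone, namely RAB3D, SERPINI1 and RAB26 (camera adjusted p = 7.87e-05, and adjusted p = 0.729 with an estimated correlation). Part of this list, RAB26 and RAB3D among it, was reported by the study on these samples, so neither count is independent evidence. The fourth member by size, the apoptosis gene BIK, differed by 0.11 on the log2 scale (SE 0.22). Of 25 mitotic genes, 17 were higher in both lines and 2 lower in both, with a median of 0.10 and 0 members past the test over all genes or adjusted over the list alone (camera adjusted p = 0.00745, and adjusted p = 0.729 with an estimated correlation). The largest differences in this list were 0.20 for AURKB (SE 0.09), 0.18 for CENPF (SE 0.14), 0.18 for MKI67 (SE 0.17) and 0.18 for CENPA (SE 0.12). CENPF turned to -0.056 with the mean of all its probe sets.

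The other secretory genes measured changed less than the 2 Rab genes. Of 30 measured Rab GTPases and exocytosis genes, 12 were higher in both lines and 7 lower in both, and 2, RAB3D and RAB26, rose when adjusted over the list alone (camera adjusted p = 0.0624), which is not independent evidence either. RIMS2 was higher by 0.49 (SE 0.22), while RAB3A differed by -0.51 (SE 0.24). Of 25 fixed zymogenic and exocrine products, 16 were on the array and 8 were measured. Of these 8, 0 passed (camera adjusted p = 0.0944), which is not evidence of no change in this fit. SPINK1, a pancreatic trypsin inhibitor, was higher by 0.50 (SE 0.23), PGC, which encodes pepsinogen C, by 0.29 (SE 0.21) and CEL by 0.16 (SE 0.24). CELA3A differed by -0.11 (SE 0.22). These genes were mostly dim, so small changes in them are hard to read. CEL read at most 62.8 and CELA3A at most 58.4 in any array, and SPINK1 at most 25.6 in HGC-27.

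No other list passed in this comparison. Camera adjusted p was 0.0746 for heat shock and immediate early genes, 0.0944 for inflammatory NF-kB targets, 0.193 for DNA replication genes, 0.195 for interferon response and 0.196 for leukocyte and endothelial genes. It was 0.267 for cholesterol synthesis, 0.522 for bHLH and ID factors and for mesenchymal genes, 0.616 for the unfolded protein response and 0.702 for gastric and intestinal lineage genes. It was 0.945 for ATF4 and amino acid stress, histone genes, hypoxia and glycolysis and epithelial genes, and 0.947 for p53 targets. Without the 2 parental arrays, an alternative chosen after seeing the data, the heat shock and immediate early list passed (adjusted p = 0.0425), while its other alternatives gave 0.1 to 0.968. The Rab and exocytosis list passed only without the block for cell line (adjusted p = 0.0339).

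The GFP control arrays differed from the parental arrays in more genes than the MIST1 arrays differed from the GFP control. In AGS 1925 genes differed by at least 1.5-fold between GFP control and parental cells, and 251 between MIST1 and GFP control. In HGC-27 these counts were 2523 and 332. In limma 34 genes passed, 17 rising and 17 falling, each with an adjusted p of 0.0452 for the genes named here. BST2, the interferon-inducible antiviral protein tetherin, rose by 1.86 on the log2 scale (SE 0.21), an understated value because the HGC-27 parental array lay under the floor. GOLGA1, a golgin of the trans-Golgi, rose by 1.61 (SE 0.17) and FAM222A by 1.45 (SE 0.17). CDKN2D, an inhibitor of cyclin-dependent kinases, rose by 1.44 (SE 0.15) and the kinase CDK14 by 1.39 (SE 0.14). MXD1, an antagonist of MYC, rose by 1.25 (SE 0.14), the Wnt receptor FZD7 by 1.14 (SE 0.12) and CACFD1 by 1.0 (SE 0.11).

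The nuclear non-coding RNA MALAT1 fell by 2.76 on the log2 scale (SE 0.23), from 3685 to 390 in AGS and from 1566 to 324 in HGC-27. The mitochondrially encoded COX3 fell by 2.65 (SE 0.18) and ND6 by 1.80 (SE 0.16). LINC02523 fell by 2.31 (SE 0.25), with both GFP control values under the floor, so its fall is at least 4.96-fold. FAM223B fell by 2.25 (SE 0.22), with the AGS GFP control under the floor, and LOC100190986 by 1.73 (SE 0.17). ATP8B1 fell by 1.93 (SE 0.23) and ALMS1 by 1.69 (SE 0.15), and like COX3 they were read by probe sets whose names mark possible cross-hybridization. Some of the ribosomal RNA control probe sets were also higher in parental cells. The 18S probe set for the middle of the molecule read 1142 in AGS parental cells against 48.2 in the GFP control and 46.8 with MIST1, and 371 against 52 and 52.7 in HGC-27. The 28S probe set for the middle of the molecule was not higher, at 2005 in parental cells and 2173 in the GFP control in AGS, and 1514 and 2250 in HGC-27.

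**Figure D3:**
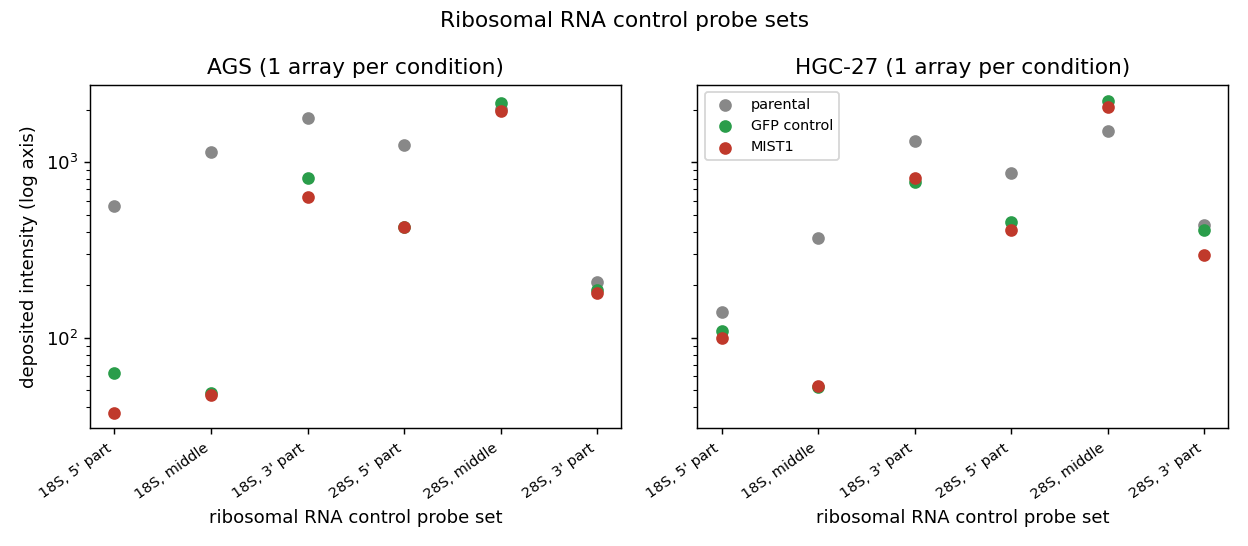
Deposited intensity (log axis) of the control probe sets for 18S and 28S ribosomal RNA in AGS (left) and HGC-27 (right), 1 point per array, grey for parental, green for the GFP control and red for MIST1. The middle 18S probe set read 1142 and 371 in the 2 parental arrays and at most 52.7 in the 4 transfected arrays.

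Several fixed lists were lower in the GFP control than in parental cells. The members named here lie outside the naming rule and were chosen after their values were seen. Of 21 unfolded protein response genes, 0 passed over all genes and 9 fell when adjusted over the list alone (median -0.33, with -0.06 in AGS and -0.54 in HGC-27, camera adjusted p = 0.000211, and adjusted p = 0.750 with an estimated correlation). These included the endoplasmic reticulum chaperones and isomerases PDIA4 at -0.75 (SE 0.14), HSP90B1 at -0.59 (SE 0.17) and HSPA5 at -0.51 (SE 0.12), and the transcription factor XBP1 at -0.42 (SE 0.10). Of 19 ATF4 and amino acid stress genes, 0 passed over all genes and 5 fell when adjusted over the list alone (median -0.31, with 0.0096 in AGS and -0.54 in HGC-27, camera adjusted p = 0.00186, and adjusted p = 0.750 with an estimated correlation). They were CHAC1 at -1.15, the cystine transporter SLC7A11 at -1.13, DDIT3 at -1.05, and the serine synthesis enzymes PSPH at -0.79 and PSAT1 at -0.57. Of 13 cholesterol synthesis genes, 0 passed over all genes and 6 fell when adjusted over the list alone (median -0.24, with -0.29 in AGS and -0.13 in HGC-27, camera adjusted p = 0.00372, and adjusted p = 0.750 with an estimated correlation), led by HMGCS1 at -0.82 (SE 0.11), STARD4 at -0.67 (SE 0.16) and INSIG1 at -0.53 (SE 0.11).

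Of 25 mitotic genes, 18 were lower in the GFP control in both lines, 0 passed over all genes and 4 fell when adjusted over the list alone (median -0.22, with -0.06 in AGS and -0.34 in HGC-27, camera adjusted p = 0.000211, and adjusted p = 0.750 with an estimated correlation). The 4 were PLK1 at -0.69, BUB1 at -0.58, HMMR at -0.41 and CCNB1 at -0.36. This comparison and that of MIST1 with the GFP control share the GFP control arrays, so their opposite directions for mitotic genes are not independent. Interferon response genes went the other way without passing (camera adjusted p = 0.0892). Of 22 measured, 13 were higher in both lines and 5 rose when adjusted over the list alone, IFI27 at 1.10, IFI44 at 1.03, IRF9 at 0.66, OASL at 0.45 and ISG15 at 0.40. In HGC-27 the median change of all genes from parental to GFP control was 0.13 on the log2 scale with the deposited values and 0.02 after quantile normalization, and changes there should be read against that shift. Quantile normalization called 75 genes, 28 rising and 47 falling.

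**Figure D4:**
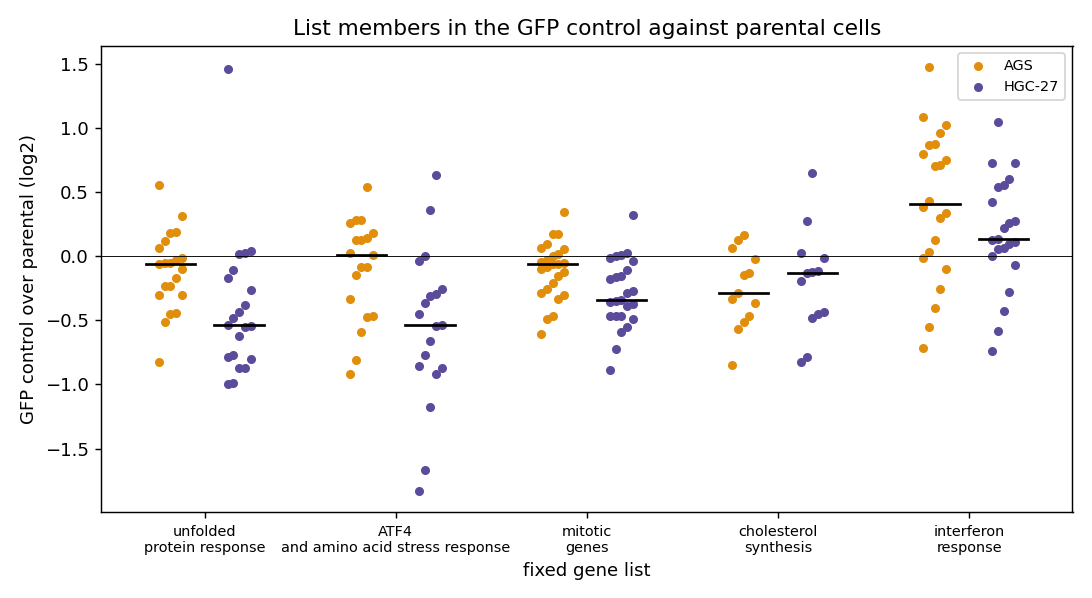
Change from parental cells to the GFP control on the log2 scale (vertical axis) for the members of 5 fixed lists (horizontal axis), 1 point per gene, with AGS in orange and HGC-27 in purple and bars at the medians. The medians in AGS and HGC-27 are -0.06 and -0.54 for the unfolded protein response, 0.0096 and -0.54 for ATF4 and amino acid stress, and 0.41 and 0.13 for interferon response.

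The 34 calls were fragile. No gene passed with no floor, with the floor at the median, with no filter, without the variance trend or without the block for cell line, and 1 passed with the mean of all probe sets of a gene. Leaving out an array raised the count, to 5324 without the AGS parental array, 4584 without the HGC-27 parental array, 924 without the AGS MIST1 array, 936 without the HGC-27 MIST1 array, 208 without the AGS GFP control and 81 without the HGC-27 GFP control.

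The comparison of MIST1-transfected with parental cells is the second control of the series. It includes any effects of transfection, sorting and sample handling, which cannot be told apart here. In limma 465 genes passed, 299 rising and 166 falling, with the same direction in both lines in each case. TGM1, a transglutaminase of the cornified envelope, rose by 2.59 on the log2 scale (SE 0.43, adjusted p = 0.0408), FAM149B1 by 2.42 (SE 0.40) and the epithelial membrane protein EMP1 by 2.10 (SE 0.37). KIAA0513 rose by 2.18 (SE 0.30) and DISP2 by 2.14 (SE 0.25). TSSK6 rose at least 4.59-fold and the non-coding RNA LINC00473 at least 4.15-fold, each with both parental values under the floor. ALPP, placental alkaline phosphatase, rose by 1.97 (SE 0.24), with the HGC-27 parental value under the floor. COX3 fell by 2.58 (SE 0.18, adjusted p = 0.0365), MALAT1 by 2.42 (SE 0.23), FAM223B by 2.20 (SE 0.22) and LOC100190986 by 1.88 (SE 0.17). LINC01107 fell by 2.10 (SE 0.37), LGALS13 by 1.91 (SE 0.33), and the histone genes H2AC17 by 2.02 (SE 0.31) and H1-4 by 1.87 (SE 0.31). The fixed histone list did not fall as a whole (camera adjusted p = 0.968). Of its 11 measured genes 3 were higher and 1 lower in both lines, with medians of -0.32 in AGS and 0.58 in HGC-27. In AGS the MIST1 values of FAM223B, LGALS13 and H1-4 lay under the floor. These comparisons share the parental arrays, so the genes they have in common are not independent findings.

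By list, MIST1-linked genes and exocytosis genes were higher than in parental cells, and stress and sterol genes were lower. The medians in AGS and HGC-27 were -0.06 and -0.57 for the unfolded protein response, -0.10 and -0.49 for ATF4 and amino acid stress, -0.40 and -0.29 for cholesterol synthesis and 0.02 and -0.20 for mitotic genes. In HGC-27 the median change of all genes was 0.09 with the deposited values and 0.01 after quantile normalization, and the HGC-27 medians should be read against that shift. Members past the test are named here outside the naming rule. Of 7 MIST1-linked genes 3 rose over all genes and 5 when adjusted over the list alone, and as above the list is not independent evidence. The 3 were RAB3D, by 1.61, RAB26, by 1.14, and CDKN1A, an inhibitor of cyclin-dependent kinases, by 0.75 (camera adjusted p = 0.00602, and adjusted p = 0.543 with an estimated correlation). CDKN1A was as high in the GFP control, where it was above parental cells by 0.78. Of 30 Rab and exocytosis genes 4 rose over all genes, these 2 Rab genes with the vesicle protein VAMP2, by 1.15, and RAB8A, by 0.36 (camera adjusted p = 0.0188, and adjusted p = 0.543 with an estimated correlation). VAMP2 and RAB8A were above parental cells by 1.08 and 0.30 in the GFP control as well. RAB3D and RAB26 were reported by the study on these samples, so this list is not independent evidence either. Of 21 unfolded protein response genes 4 fell, SEC24D by 0.92, PDIA4 by 0.90, SDF2L1 by 0.73 and XBP1 by 0.53 (camera adjusted p = 0.000638, and adjusted p = 0.862 with an estimated correlation). Of 19 ATF4 and amino acid stress genes 3 fell, DDIT3 by 1.16, PSPH by 0.78 and PSAT1 by 0.62 (camera adjusted p = 0.00602, and adjusted p = 0.862 with an estimated correlation). Of 13 cholesterol synthesis genes 2 fell, HMGCS1 by 0.94 and INSIG1 by 0.61 (camera adjusted p = 0.00285, and adjusted p = 0.543 with an estimated correlation). Of 25 mitotic genes 1 fell, BUB1, by 0.55 (camera adjusted p = 0.0308, and adjusted p = 0.862 with an estimated correlation).

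The count of 465 genes became 0 with the floor at the median, with no filter, without the variance trend or without the block for cell line. It was 202 with no floor, 73 with the mean of all probe sets of a gene and 714 after quantile normalization. It was 5333 without the AGS parental array, 5220 without the HGC-27 parental array, 838 without the AGS GFP control and 879 without the HGC-27 GFP control. When MIST1 was set against the mean of both controls, 0 genes passed in limma, with 1615 at an unadjusted p under 0.05 where chance gives 686 and a smallest adjusted p of 0.231. That count was 3225 without the AGS parental array, 3481 without the HGC-27 parental array, 19 without the AGS GFP control, 61 without the HGC-27 GFP control, 87 without the AGS MIST1 array and 28 without the HGC-27 MIST1 array.

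The 2 lines differed far more from each other than any conditions did. Averaged over the 3 conditions, 8262 of 13730 genes passed in limma, 4544 higher in AGS and 3718 higher in HGC-27, while after quantile normalization 4093 were higher in AGS and 4464 in HGC-27. All 17 measured epithelial genes were higher in AGS. KRT18, a keratin of simple epithelia, was 618-fold higher (adjusted p = 3.49e-07), the adhesion molecule EPCAM 227-fold, and KRT19 and MAL2 at least 563-fold and at least 412-fold, since their 3 HGC-27 values lay under the floor. Of 14 gastric and intestinal lineage genes, 8 were higher in AGS and 6 did not pass. VIL1, which encodes villin, was at least 166-fold higher, the intestinal cadherin CDH17 67.5-fold, the gastric trefoil peptide TFF1 60.1-fold and SOX2 at least 35.9-fold. Other genes higher in AGS were TSPAN8, at least 555-fold, GATM, 332-fold, PLA2G2A, 331-fold, ANXA3, 301-fold, and GALC, at least 282-fold.

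HGC-27 had the higher level of mesenchymal genes, 14 of 17 measured. The transcription factor SNAI2 was at least 103-fold higher than in AGS, TWIST1 98.9-fold (adjusted p = 3.72e-07), the matrix protein SPARC at least 99.6-fold and the collagen crosslinking enzyme LOX 59.9-fold. The 3 members that did not pass, named outside the rule, were CDH2, COL6A1 and FBN1, at -0.06, -0.17 and -0.04 on the log2 scale of AGS over HGC-27. GJA1, which encodes connexin 43, was 260-fold higher in HGC-27, the fibrillar collagen COL3A1 257-fold, cyclin D2 (CCND2) 194-fold, and EFHD1 181-fold. The RNA-binding protein gene QKI was at least 185-fold higher, the Wnt inhibitor APCDD1 at least 173-fold and KIF26A at least 171-fold. MAGEA6, a cancer-testis antigen, was 182-fold higher, with 2 of its 3 AGS values under the floor. In CDH17, TFF1, GATM, ANXA3, GJA1 and CCND2 1 of the 3 dim values lay under the floor, so these folds are understated. In all genes named with a fold between the lines, the dim values were under 50.53, except 1 of MAGEA6, and so near background that the folds are rough. The AGS values of KRT18 were also near the array maximum. KRT18, COL3A1 and MAGEA6 were read by probe sets whose names mark possible cross-hybridization.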

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

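In this part, the tests of RNA degradation and of a response to transfection were chosen after the results were seen. The test of unspliced or untailed RNA was not.

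Of the ribosomal RNA control probe sets, which no comparison uses, 3 were at least 1.5-fold higher in the parental array than in both transfected arrays of the same line, in AGS and in HGC-27. The smaller excess of the 2 lines over the higher transfected array was 7.04-fold for the 18S middle probe set, 1.62-fold for the 18S 3' probe set and 1.92-fold for the 28S 5' probe set. Degraded parental RNA stays open, since the 3' to 5' log2 difference of the ACTB and GAPDH control probe sets moved by at most 0.0881, but in these probe sets the highest reading was 76.4% to 94.4% of the array maximum, too near it to decide. More unspliced or untailed RNA in the labelled parental target may account for part of the excess. Probe sets without a named gene were higher in parental cells, relative to named ones of like level, by a median of 0.00992 log2 in AGS and 0.0882 in HGC-27. They were picked for lacking a gene and not for reading untailed RNA, so these small medians do not decide it. A response of the cells to nucleofection and sorting also stays open, since the interferon list missed the threshold (camera adjusted p = 0.0892), and with 1 array per condition and line sample handling and transfection cannot be told apart.

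Left out of the gene counts were 4964 probe sets past the filter that list several genes, none, XIST or a Y-linked gene. Of these, 3 were at least 1.5-fold above both controls in both lines and 0 were as far below them. Their smallest folds of MIST1 over a control were 1.83, 1.72 and 1.58. No gene is named from them, and no explanation was tested.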

How the results depend on the processing

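The settings without the parental comparisons and without the 2 parental arrays were chosen after seeing the data; where no cause is given, the cause was not tested. In limma, 0 genes passed for MIST1 against the GFP control under the 8 other settings with all 6 arrays, 55 with only the 4 arrays compared, and 1 to 57 with 1 array left out. For MIST1 against parental, 714 genes passed after quantile normalization, 202 with no floor, 73 with the mean of all probe sets of a gene and 860 with only the 4 arrays compared. With the floor at the median, no filter, no variance trend or no block for cell line the count was 0, and with 1 array left out it was 465 to 5333. For the GFP control against parental, 75 genes passed after quantile normalization, 1 with the mean of all probe sets and 915 with only the 4 arrays compared. With no floor, the floor at the median, no filter, no trend or no block it was 0, and with 1 array left out 81 to 5324. MIST1 against both controls gave 0 in the 8 other settings with 6 arrays and 19 to 3481 with 1 left out. AGS against HGC-27 gave 6368 to 9947 genes in all settings; after quantile normalization 4093 were higher in AGS and 4464 in HGC-27, so the larger group changed. The Boolean count was 102 up and 41 down at 1.2-fold and 2 up and 0 down at 2-fold. It was 26 up and 2 down without the parental comparisons, and 19 to 76 up and 0 to 35 down with 1 array left out, since fewer conditions then have to be met. The real pair of MIST1 arrays ranked 2 of 9 in each setting tried. The correlation of the lines was 0.27 with the floor at the median and 0.13 with no filter. Lists past the threshold were 0 in all 3 comparisons with an estimated correlation, where the 2 residual degrees of freedom leave little room to pass. With fry they were 0 for MIST1 against the GFP control, 2 for MIST1 against parental, and 0 for the GFP control against parental. Direction turned for genes that had not passed in the fit of all 6 arrays, among them TNNC1, which had passed with only the 4 arrays compared. CENPF was -0.056 with the mean of all probe sets, and CDH2 0.042 without the 2 parental arrays. With 1 array left out, MIST1 over the GFP control ranged from -0.17 to 0.031 for BHLHA15, -0.11 to 0.33 for BIK, -0.013 to 0.33 for CEL, -0.25 to 0.036 for CELA3A and -1.15 to 0.0023 for TNNC1. AGS over HGC-27 ranged from -0.14 to 0.042 for CDH2 and -0.26 to 0.20 for FBN1. Of the named-gene values under other settings, 97 for the GFP control against parental and 180 for MIST1 against parental lost the threshold with direction kept. The number of arrays limits the precision of all of these values.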

Other observations

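In this part, the tests of a stronger transfection effect, of swapped labels and of the BHLHA15 probe set were chosen after the results were seen. The others were not.

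The Boolean rule gave 17 genes upward and 0 downward for the MIST1 arrays. Chance of the rule as the whole cause at 1.5-fold is argued against by the choices that only exchange MIST1 and GFP control arrays. Both GFP control arrays gave 1 gene upward. The AGS GFP control with the HGC-27 MIST1 array gave 0, and the AGS MIST1 array with the HGC-27 GFP control gave 2. Choices with 1 parental array gave at most 4, but the parental difference shared by the lines likely keeps those counts low. With so few choices chance is not excluded. However, simulated arrays without any change gave a mean of 7.95 and at most 13. Those arrays lacked the real difference between parental and transfected arrays, so they are only a rough chance level. At 1.2-fold the highest mixed choice of arrays gave 56 genes against 102, so many of those 102 could arise by chance of the rule. A shift of scale of the MIST1 arrays is argued against by quantile normalization, which left 17 genes, 16 of them shared. For a stronger transfection effect in the MIST1 arrays, a first test on the 17 genes did not decide. Their median change with GFP was 0.24 (AGS) and 0.33 (HGC-27) of that with MIST1. Of the 17, 11 in AGS and 16 in HGC-27 were already higher in the GFP control than in parental cells. In HGC-27 the median over all genes tested was itself higher by 0.13 log2, and in AGS it was 0. A second test took other genes changed 2-fold with GFP in one line and read them in the other. Their further median change with MIST1 was -0.0081 (HGC-27) and 0.0977 (AGS) times that with GFP. The limit, a ratio under 0.1 in both lines, was also set after the results were seen, and AGS met it narrowly. Of the genes read, 55.4% moved further in AGS and 42.3% in HGC-27. These small ratios argue against a stronger transfection effect as the whole cause but not as a part.

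The BHLHA15 probe set did not rise in the arrays labelled MIST1. A swap of the MIST1 and GFP control labels in one line is argued against by the changes in the 2 lines, which correlated at 0.21 across genes. That the probe set does not read the construct may be why it stayed flat, with a change over the GFP control of at most 0.0764 log2 in size in either line. The labels give no construct sequence, which keeps this open.

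The 6 arrays divide into 3 and 3 in 10 ways, too few for a share under 0.05. The split by cell line gave 8262 genes, 1 of the 10 splits with as many, and the highest of the others gave 0. Those other splits leave the large difference between the lines in their residual spread. Their 0 was therefore nearly fixed in advance and tells nothing about chance.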
